A study of Arabidopsis thaliana with 18 samples.

How the data were processed

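RNA of 5-day-old Arabidopsis seedlings was labelled with biotin and hybridised to Affymetrix arrays, per the labels. The 18 arrays fall into 6 groups of 3, for Col-0, gun1-9 and gun5 with and without 5 uM norflurazon. The authors deposited 1 table of probe-set intensity values, 1 column per array. The values are linear, positive and nearly equal in median and quartiles between arrays, so they were normalized before they were deposited. GCRMA and MAS5 are named in the submitters' processing notes, with no role or version. GCRMA estimates background from probe sequence and can push dim probe sets to a narrow band of low values, so that changes starting there depend on that step. Normalization between arrays assumes that most transcripts do not change, and a shift of many genes one way would be partly removed. Every value column was used, and no array was left out.

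Of 22810 rows, 64 control probe sets were left out and 22746 were tested. The platform annotation supplied with the data names 1 gene for 13513 of them and several for 503, and does not list 8730. Symbols were updated through a reference gene table of assembly TAIR10.1, in which 13436 of the 13513 were found. Only 1580 carry a symbol other than a locus code. No gene was named from a probe set with several genes, and no coordinates are given, because the deposited values and the platform annotation name no genome build. Intensities were transformed to log2(intensity + 1). The group means of all 18 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 4.48). Contrasts were 2-sided, and p-values were adjusted by the Benjamini-Hochberg method within each contrast, with calls under 0.05. No covariate was used. Figures were drawn with matplotlib 3.10.9.

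Pearson's r between replicate arrays was at least 0.992 within groups, across probe sets, and no array pair shared more than 0.440% identical values. Dim probe sets were defined by a log2 level of 2.26, the mean first quartile of the arrays.

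Before the data were examined, 18 gene lists with 376 genes were fixed, together with the contrasts, the alternatives and the rule for named genes. Only 78 of those genes have a probe set that matches them alone, so that 9 lists with at least 3 measured members were tested. Camera was used with a correlation of 0.01, and again with an estimated one, on 1 probe set per gene, the one with the highest mean. Named genes are the 10 largest rises and 10 largest falls among called genes with non-overlapping groups in each norflurazon response, 10 per direction in each difference of response from Col-0, and 5 per direction in the other contrasts, plus members of the lists.

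The fit was tested on simulated data with the spreads of these arrays. For the norflurazon response in Col-0, with 22746 probe sets, 99.0% of 100 probe sets changed by 1 log2 unit were called, and for the difference of response between gun1-9 and Col-0 81.0%. At 2 log2 units 100% were called in each. Of lists of unchanged probe sets, 1.00% had p under 0.05 in camera. The simulated probe sets varied independently of each other, so this does not test camera on lists whose genes vary together. In the fixed lists the estimated correlation reached 0.46.

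Alternatives were a replicate block, a filter on dim probe sets, quantile normalization, centring each array on its median, a fit on only the arrays compared, eBayes with trend and robust settings, a 2-fold minimum, log2(intensity + 16), and each array left out in turn. The filter left out the probe sets with the lowest means over all arrays, by a quantile of these means. It did not use the dim level given above. For lists, all probe sets of a member and an estimated correlation were tried. Lists of the plastid and mitochondrial genomes, 17 symbol families and 22 further seed genes, and a fit without the plastid-genome probe sets, were added after seeing the data.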

Results

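Transcript levels were measured in Arabidopsis thaliana seedlings of the wild type Col-0 and of the mutants gun1-9 and gun5, grown in the light for 5 days with or without 5 uM norflurazon. Norflurazon is a herbicide that blocks carotenoid synthesis, so that plastids are damaged by light. The gun (genomes uncoupled) mutants were isolated because nuclear photosynthesis genes stay active in them when plastids are damaged. GUN1 is a pentatricopeptide repeat protein of the plastid and GUN5 is the H subunit of magnesium chelatase, an enzyme of chlorophyll synthesis. The 6 groups had 3 arrays each, 18 in all, described in the series design as biological replicates. Median intensity per array lay between 14.7 and 16.3. The number of arrays limits the precision, since each group mean rests on 3 values. Fold changes are on the log2(intensity + 1) scale and are given with the standard error (SE) of the limma fit; this scale understates changes of dim probe sets. Levels are mean intensity ± SD (n = 3).

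The transcripts of the mutated genes were not analysed here, because the annotation used names no probe set for either alone. Their levels need not check the labels, which do not say what the alleles change. Of the 19 marker genes chosen in advance, 1 had a probe set of its own.

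The first question was which genes respond to norflurazon in the wild type. In Col-0, the measured nuclear genes of photosynthesis fell together, but most genes of each list were not measured. The lists held 3 of 20 fixed antenna genes, 5 of 30 photosystem, 4 of 26 Calvin cycle and 9 of 30 tetrapyrrole genes. All 3 measured antenna genes fell, with LHCB4.2 (AT3G08940), an antenna protein of photosystem II, going from 4384 ± 393 to 249.5 ± 44.9 (log2 change -4.14). All 5 measured nuclear genes of the photosystems and electron transport fell, among them PSAE1 (PSAE-1) of photosystem I (log2 change -3.08) and PSBY of photosystem II (-3.07). All 4 measured genes of the Calvin cycle and photorespiration fell too, including PRK, phosphoribulokinase (-3.09), and SBPASE, sedoheptulose bisphosphatase (-3.13). Of 9 measured tetrapyrrole genes, 8 fell and 1 was not called. PORB (AT4G27440), a protochlorophyllide oxidoreductase and the marker gene with a probe set of its own, had the largest fall of that list, from 957.2 ± 159 to 34.17 ± 4.57 (log2 change -4.76). HEMA2, a glutamyl-tRNA reductase gene, had a log2 change of 0.05 and was not called. The median log2 change was -3.26 for the antenna list, -2.84 for the photosystem list, -2.75 for the Calvin cycle list and -1.52 for the tetrapyrrole list. Adjusted over the list alone, the counts of fallen genes were the same 3, 5, 4 and 8. The list test (camera) gave adjusted p = 2.79e-06, 8.65e-10, 2.84e-08 and 8.65e-10 in that order, and adjusted p = 0.00236, 0.00147, 0.00236 and 0.00236 with an estimated correlation.

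The largest named fall in Col-0 was that of AT5G48490, from 850.1 ± 109 to 5.68 ± 0.726 (log2 change -6.99 ± 0.19 SE, adjusted p = 2.16e-14). The next largest log2 changes of named genes were those of AT2G25510 (-6.83), AT2G43550 (-6.54), AT1G70820 (-6.35), AT2G34620 (-6.07) and AT1G66100 (-5.95). AT1G75460 (-5.91), AT4G12830 (-5.87), AT1G21500 (-5.40) and AT2G03750 (-5.02) followed. Among probe sets with no gene name here, the largest fall was from 7471 ± 611 to 18.98 ± 2.18 (log2 change -8.55).

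Named genes that rose in Col-0 were led by AT2G21640, listed among the mitochondrial stress genes as UPOX, from 7.88 ± 3.21 to 575.2 ± 34.0 (log2 change 6.08 ± 0.25 SE, adjusted p = 2.66e-12). AT1G17960 rose by 5.65, AT1G12010 by 4.73, AT2G04050 by 4.72, AT2G47780 by 4.18, GAT1_2.1 by 3.84, AT2G47680 by 3.80, AT1G19530 by 3.59, the mitochondrial heat shock gene AT5G51440 (HSP23.5) by 3.57 and ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle and the measured member of the seed and early seedling list, by 3.52. AT2G04050 started at 3.25 ± 0.488, below the dim level of log2 2.26. Of the 3 measured mitochondrial stress genes (11 fixed) 2 rose, and the list test gave adjusted p = 0.0182, or adjusted p = 0.0524 with an estimated correlation. The third, NDB2, had a log2 change of -0.32 and was not called. All 4 measured flavonoid and anthocyanin genes (20 fixed) rose. DFR (AT5G42800), dihydroflavonol reductase, went from 49.64 ± 22.6 to 310.6 ± 87.8 (log2 change 2.71), and the glycosyltransferase genes UF3GT (AT5G54060) and AT4G14090 rose by 3.24 and 2.76. That list had adjusted p = 0.00162, or adjusted p = 0.0797 with an estimated correlation. The counts of both lists were the same adjusted over the list alone.

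In all, 8936 of 22746 probe sets were called in Col-0, 5506 higher and 3430 lower. At least 2-fold, 948 were higher and 1479 lower. When each array was centred on its own median, 49.7% of the calls were higher, against 61.6% with the deposited scaling.

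The same comparison in the mutants gave smaller falls of the measured nuclear photosynthesis genes. In gun1-9, 2 of the 3 antenna genes fell (list median -0.83) and LHCB4.1 had a log2 change of -0.16 without a call. All 5 photosystem genes fell (median -0.69), as did 3 of the 4 Calvin cycle genes (median -1.06), and of the 9 tetrapyrrole genes 7 fell and HEMA2 rose by 0.66 (median -0.44). Adjusted over the list alone, 4 Calvin cycle and 8 tetrapyrrole genes fell in gun1-9, and the other counts of these 4 lists in both mutants were the same. In gun5, all 3 antenna genes fell (median -1.52), as did all 5 photosystem genes (median -0.72), 3 of the 4 Calvin cycle genes (median -0.58) and 4 of the 9 tetrapyrrole genes (median -0.27), while HEMA2 rose by 1.11. RCA, rubisco activase, had log2 changes of -1.89 in Col-0, -0.18 in gun1-9 and 0.05 in gun5, the last 2 not called. PORB had log2 changes of -3.29 in gun1-9 and -3.85 in gun5. The list test gave adjusted p of 0.014, 0.000232, 0.000265 and 0.000211 in gun1-9 and 6.5e-05, 2.66e-05, 0.0101 and 0.0101 in gun5, in the order antenna, photosystem, Calvin cycle, tetrapyrrole. With an estimated correlation, the antenna list in gun1-9 had adjusted p = 0.0581, and in gun5 the Calvin cycle and tetrapyrrole lists had adjusted p = 0.112 and 0.140. In gun1-9, 8247 probe sets were called, 4669 higher and 3578 lower, and in gun5 6565, 3564 higher and 3001 lower. At least 2-fold, 961 were higher and 1187 lower in gun1-9, and 648 higher and 865 lower in gun5.

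**Figure D1:**
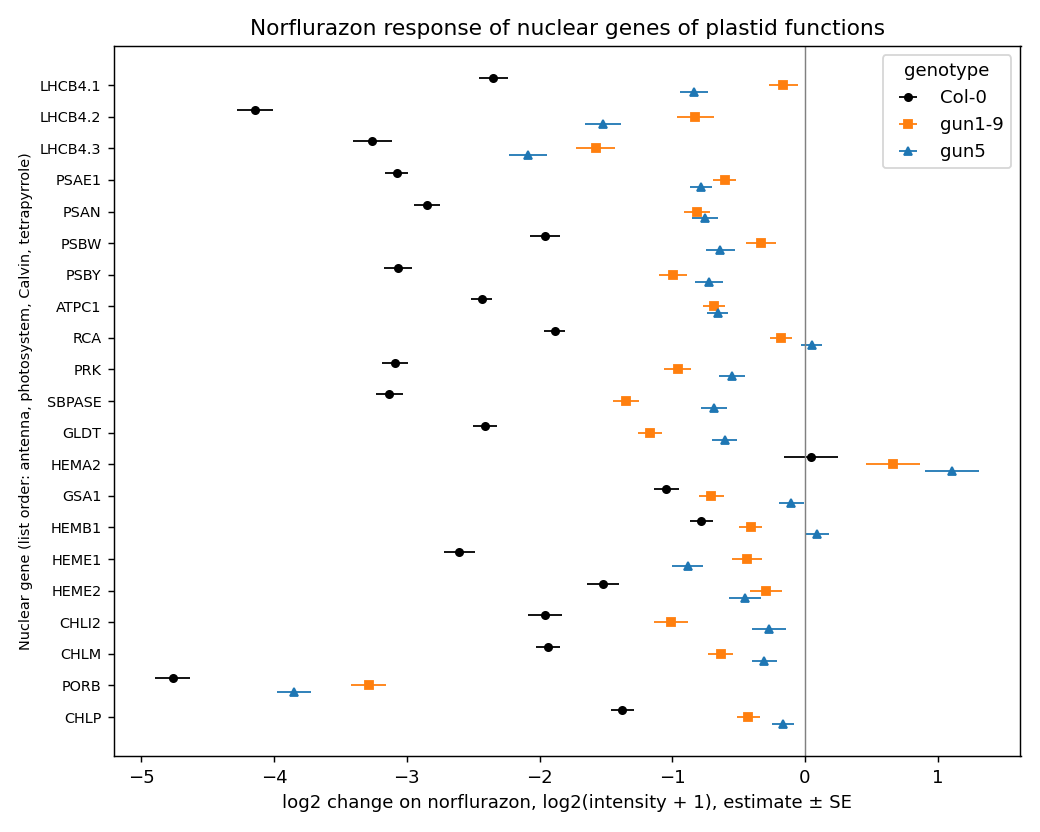
The plot gives the log2 change on norflurazon (horizontal axis, estimate with SE bars) for each measured nuclear gene of the antenna, photosystem, Calvin cycle and tetrapyrrole lists (vertical axis) in Col-0, gun1-9 and gun5. LHCB4.2 sits at -4.14 in Col-0, -0.83 in gun1-9 and -1.52 in gun5.

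Several rises were common to the 3 genotypes. AT2G21640 rose by 5.36 in gun1-9 and 3.84 in gun5, AT1G12010 by 5.12 in both, AT2G04050 by 6.58 and 5.36, AT1G17960 by 4.90 and 4.26, AT5G51440 by 4.78 and 3.75, and ICL by 4.45 and 4.87. GAT1_2.1 rose by 3.67 in gun5. The mitochondrial stress list had adjusted p = 0.0027 in gun1-9 and 0.0101 in gun5, and with an estimated correlation adjusted p = 0.0226 and 0.0458. GSTU20 (AT1G78370), a glutathione transferase gene, fell with log2 changes of -6.26 in gun1-9 and -5.66 in gun5. Further large falls of named genes in gun5 were those of AT5G48490 (-6.13), AT3G53980 (-5.49), AT1G13650 (-5.10), AT1G66100 (-4.79), AT4G33550 (-4.68), AT2G43550 (-4.51), AT3G13650 (-4.21) and AT5G01015 (-4.13). CCS (AT1G12520), the copper chaperone of superoxide dismutase, rose by 3.19 in gun5 and AT2G43140 by 3.36. AT2G41730 rose by 4.81 in gun1-9. Levels of AT1G13650 in treated gun5 and of AT2G04050 in each untreated group were below the dim level.

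Plastid-encoded transcripts fell further in gun1-9 than in gun5. The difference of response between these mutants was called and negative for 26 of the 29 measured plastid-encoded genes of the list (median -4.10), and for 28 when adjusted over the list alone. On norflurazon, 28 of the 29 fell in gun1-9 (median log2 change -4.12), 19 fell in Col-0 (median -0.90), and in gun5 5 fell and 2 rose (median -0.08). Adjusted over the list alone, 29 fell in gun1-9, and the counts in Col-0 and gun5 were the same. In gun1-9, psbC of photosystem II went from 2376 ± 459 to 6.27 ± 2.58 (log2 change -8.40 ± 0.24 SE, adjusted p = 1.13e-13), and the log2 changes of psaA of photosystem I and psbA of photosystem II were -7.96 and -6.87. For psbC, psaA and psbA the log2 changes were -3.56, -4.13 and -3.17 in Col-0 and -0.93, -1.58 and -0.81 in gun5. Among the largest falls of named genes in gun1-9 were also ndhE (-6.22), petL (-6.17), ndhJ (-6.09), psbB (-6.02) and ndhA (-5.93). In Col-0, rbcL, rpoC1 and rpoA had log2 changes of -0.36, -0.19 and 0.13 and were not called, whereas in gun1-9 the log2 changes were -4.87, -4.68 and -3.42. The list test gave adjusted p = 1.85e-38 in gun1-9, 8.65e-10 in Col-0 and 0.136 in gun5, and with an estimated correlation adjusted p = 0.0119, 0.0893 and 0.647. The control probe set for 25S ribosomal RNA, which was not tested, was at 37.1 ± 11.3 in untreated and 2147 ± 1124 in treated gun1-9.

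**Figure D2:**
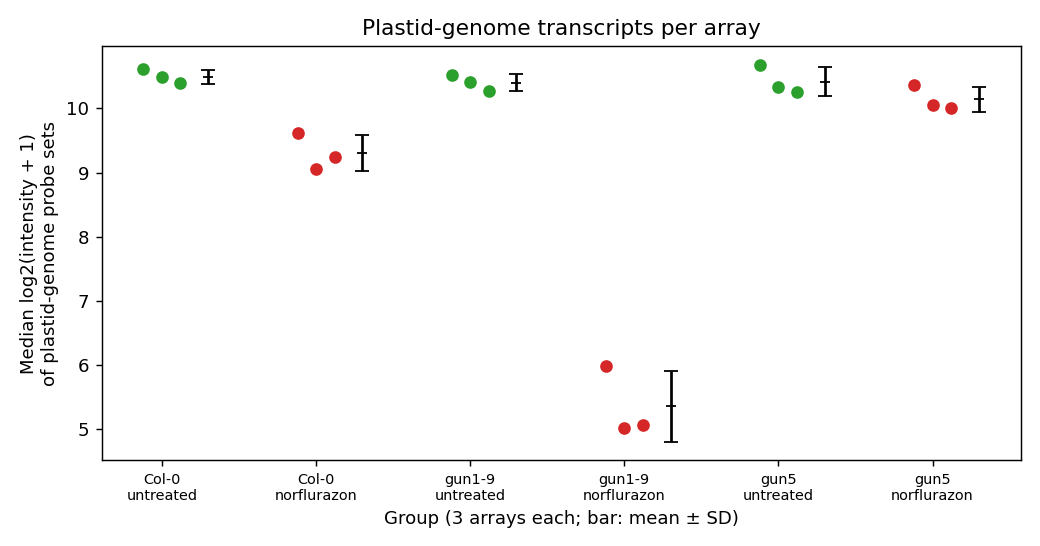
Each point is 1 array and gives the median log2(intensity + 1) of the 69 plastid-genome probe sets (vertical axis) in each group (horizontal axis), with bars for the mean and SD of 3 arrays. Treated gun1-9 lies at 5.36, against 9.30 in treated Col-0 and 10.14 in treated gun5.

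The second question was whether the response differs between genotypes, tested as the difference of the log2 changes. The measured nuclear photosynthesis genes fell less in both mutants. The difference from Col-0 was called and positive for all 3 antenna, 5 photosystem and 4 Calvin cycle genes in gun1-9 and in gun5, and for 6 of 9 tetrapyrrole genes in gun1-9 and 9 of 9 in gun5. Adjusted over the list alone, 9 tetrapyrrole genes passed in gun1-9, and the other counts were the same. The median difference was 2.18 and 1.51 for the antenna list, 2.03 and 2.09 for the photosystem list, 1.74 and 2.19 for the Calvin cycle list, and 0.95 and 1.07 for the tetrapyrrole list, gun1-9 first. The camera test gave adjusted p of 1.18e-07, 1.51e-12, 1.23e-09 and 1.54e-09 in gun1-9 and 7.88e-06, 1.9e-11, 9.46e-11 and 1.9e-11 in gun5 for these 4 lists. With an estimated correlation the largest adjusted p was 0.00186 in gun1-9 and 0.00351 in gun5. Both measured carotenoid genes, ZISO (Z-ISO) and LCYB (LYC), fell in Col-0 (-1.12 and -1.14), and their differences from Col-0 were called and positive in both mutants (1.14 and 1.01 in gun5).

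AT3G28270 fell by 4.85 in Col-0, from 113.7 ± 21.1 to 2.98 ± 0.826, and was at 137.8 ± 16.1 in treated gun1-9 and 115.9 ± 34.4 in treated gun5. The difference of response was 5.06 ± 0.28 SE in gun1-9 (adjusted p = 1.08e-09) and 5.10 ± 0.28 SE in gun5 (adjusted p = 1.39e-09). Its level in treated Col-0 was below the dim level, so that the size of these differences depends on the background step and on the constant added. AT1G75460 and AT1G78995 were likewise among the largest positive differences of both mutants with a gene name, with 4.07 and 4.06 in gun5. In gun1-9 these also included AT1G60590 (5.29), AT4G28080 (4.34) and AT5G48490 (4.27), and in gun5 AT1G70820 (4.41), AT2G25510 (4.18), AT3G62550 (4.12), AT5G27290 (3.97), the sucrose phosphate synthase gene ATSPS4F (3.83), AT4G37560 (3.82) and AT4G12830 (3.81).

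Of the 1479 probe sets at least 2-fold lower in Col-0, the median log2 change was -1.64 in Col-0, -0.84 in gun1-9 and -0.60 in gun5. The smaller fall was itself called for 877 of them (59.3%) in gun1-9 and 1029 (69.6%) in gun5. Choosing genes by their fall in Col-0 favours a larger value there. Among the 1187 chosen by their fall in gun1-9, the medians were -1.07 in Col-0 and -1.50 in gun1-9, and among the 865 chosen in gun5 they were -1.13 in Col-0 and -1.40 in gun5. Of the 948 probe sets higher in Col-0, a smaller rise was called for 220 in gun1-9 and 307 in gun5.

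Other genes rose in treated gun1-9. UGT73C1 (AT2G36750), a glycosyltransferase gene, rose by 5.22 to 308.6 ± 38.0 and by 3.14 in gun5, with a difference of response of 4.61 ± 0.19 SE between gun1-9 and Col-0 (adjusted p = 3.87e-11). AT2G29370 (4.77), UGT84A3 (4.61) and AT1G09500 (4.54, with levels below the dim level in every untreated group and in treated Col-0) had similar differences. AT3G16670 (-5.68) and AT1G23130 (-5.52) had the most negative ones among probe sets with a gene name, and AT3G16670 was at 23.76 ± 8.93 in treated gun1-9 and 1062 ± 98.1 in treated Col-0. The plastid-encoded list differed from Col-0 in opposite directions: 26 of 29 genes were lower in gun1-9 (median -3.04, adjusted p = 5.22e-41) and 18 were higher in gun5 (median 0.85, adjusted p = 1.9e-11). With an estimated correlation these became adjusted p = 0.00186 and 0.0758. The counts were 27 and 19 adjusted over the list alone. Largest among the named plastid genes in gun1-9 were rpoC2 (-4.89), psbC (-4.84), petL (-4.80), rpl20 (-4.57), rbcL (-4.52), rpoC1 (-4.49) and rpl14 (-4.42). AT3G02480 (-4.81, adjusted p = 0.0138) was also among the most negative named differences.

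Of the 4 measured flavonoid and anthocyanin genes, 3 responded in the opposite direction in gun5. DFR fell from 73.01 ± 15.9 to 12.45 ± 4.84 in gun5 (log2 change -2.50), and rose by 2.19 in gun1-9. Of the 4 genes, 3 fell in gun5 (adjusted p = 0.0243, and adjusted p = 0.211 with an estimated correlation) and 2 rose in gun1-9 (adjusted p = 0.035, and adjusted p = 0.198 with an estimated correlation). The difference of response of DFR between gun5 and Col-0 was -5.21 ± 0.60 SE (adjusted p = 6.41e-06). UF3GT (-4.31) and AT4G14090 (-3.63) followed. These differences include the rises in Col-0, and the median log2 change of the 4 genes in gun5 itself was -0.97. All 4 measured flavonoid and anthocyanin genes differed from Col-0 in gun5 (median -3.97, adjusted p = 3.47e-06, and adjusted p = 0.0158 with an estimated correlation). The fourth gene, AT5MAT, had a log2 change of -0.16 in gun5 without a call. Its values in treated gun5 (log2 1.98 to 2.17) were below the dim level. In gun1-9, AT4G14090 was called lower (-2.29) and the other 3 were not called (list median -0.52, adjusted p = 0.0583). Adjusted over the list alone, 4 genes differed in gun5 and 2 in gun1-9. Compared by level on norflurazon, all 4 genes were called lower than in treated Col-0 in both mutants. The median log2 difference was -1.13 in treated gun1-9 and -3.76 in treated gun5. Further negative differences of response in gun5 were those of AT2G47780 (-3.53), AT2G47680 (-3.11), AT4G12490 (-2.89), AT4G10270 (-2.81), AT2G43620 (-2.76), chr31 (-2.63, with levels below the dim level in untreated Col-0 and in gun5) and GSTU20 (-2.62). The difference for AT4G10270 was not called in 9 of 26 alternative settings.

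**Figure D3:**
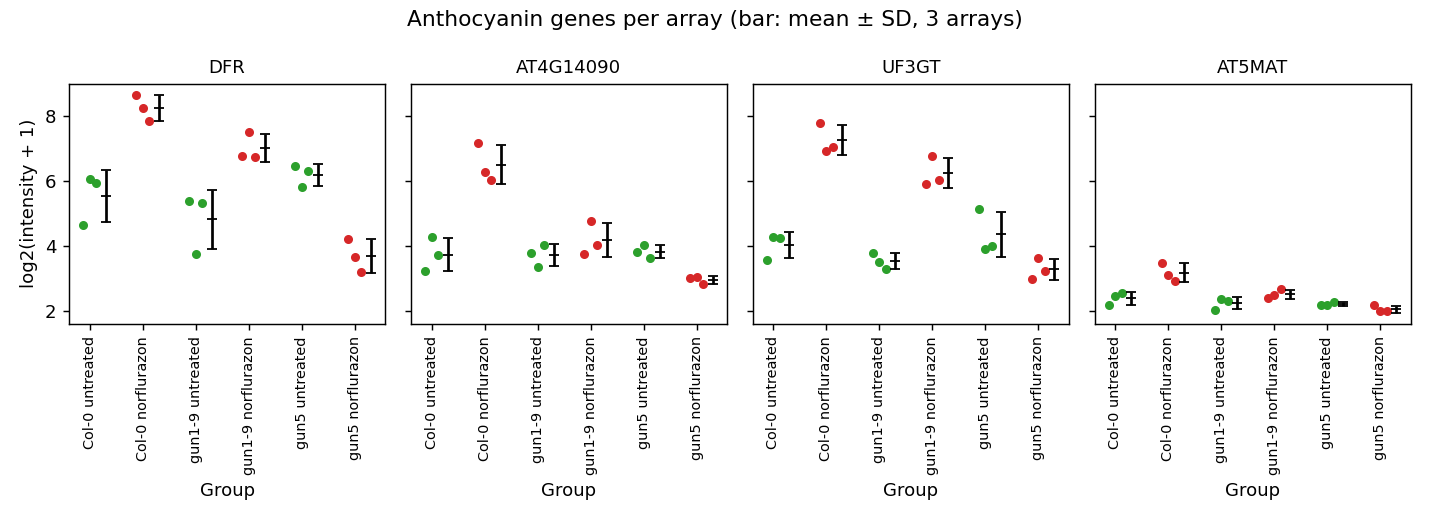
Each panel shows 1 flavonoid or anthocyanin gene, each point 1 array, as log2(intensity + 1) (vertical axis) by group (horizontal axis), with bars for the mean and SD of 3 arrays. DFR changed by 2.71 in Col-0, 2.19 in gun1-9 and -2.50 in gun5.

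The difference of response from Col-0 was called for 3476 probe sets in gun1-9, 1835 higher and 1641 lower, and for 3831 in gun5, 1986 higher and 1845 lower. With each array centred on its median, 66.3% of the gun5 calls were higher, against 51.8% with the deposited scaling. Both lists of calls shared 1297 higher probe sets, where independent lists would share 160.2, and 867 lower ones, where independent lists would share 133.1. Simulated arrays with no effect gave 0 shared calls, but hardly any probe set is called without an effect, so this does not measure the part of the shared Col-0 arrays. Across probe sets, which are not independent replicates, the 2 differences correlated with r = 0.699, and 0.501 in the simulations. Their covariance was 0.240, and 0.0225 in the simulations, a difference of 0.218. The 3 Col-0 arrays per treatment could not be divided with at least 2 on each side, so part of the excess of shared calls may come from them.

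The mutants were also compared with each other. Their responses differed for 1241 probe sets, 544 higher and 697 lower in gun1-9 than in gun5. Among probe sets with a gene name, the most negative differences were plastid-encoded: psbC (-7.46), psaA (-6.38), ndhE (-6.24), psbA (-6.05) and rpl20 (-5.74). DFR (4.69), AT4G12490 (3.92), AT3G49160 (3.89), UF3GT (3.78) and AT2G29370 (3.57) were the most positive ones with a gene name.

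Without norflurazon, in gun1-9 90 probe sets were called against Col-0, 33 higher and 57 lower, and in gun5 380, 198 higher and 182 lower. ICL was lower in both, at 17.37 ± 11.5 in gun1-9 and 7.94 ± 5.90 in gun5 against 260.4 ± 202 in Col-0 (log2 difference -3.80 and -4.71). AT1G04560 was lower in both (-3.51 and -3.38), AT4G36600 (-2.08), AT5G66780 (-1.78) and AT2G21340 (-1.56) in gun1-9, and AT3G15670 (-3.44), AT3G17520 (-2.66) and AtLEA4-1 (-2.65), late embryogenesis abundant genes, in gun5. The lower levels of AT1G04560, AT3G17520 and AtLEA4-1 were below the dim level. Higher in gun1-9 were AT1G13650 (1.47), AT5G59330 (1.37), AT5G01870 (1.32), Hsp70-2 (1.24) and AT5G01740 (1.11), and in gun5 AT4G12490 (2.88), AT2G43620 (2.46), AT4G12500 (2.27), AT1G13650 (2.04) and AT2G24600 (1.85). A probe set with no gene name here was at 42.2 ± 14.9 in untreated gun1-9 and 736.3 ± 41.5 in untreated Col-0. The control probe set U12639, which was not tested and whose target is not given in the sources used here, was at 596.6 ± 68.0 in untreated gun5, 2.84 ± 0.0153 in untreated Col-0 and 3.78 ± 0.554 in treated gun5. It was as low in the remaining groups. None of the 9 fixed lists tested with camera was called in these 2 comparisons. The limma counts fell to 1 and 123 when only the 6 arrays compared entered the fit, and to 27 and 180 without Col-0 control replicate 3. They were 34 for gun1-9 without its control replicate 3, 59 and 160 without gun5 control replicate 3, and 196 and 234 for gun5 without its control replicates 1 and 2. Of the named results of these 2 comparisons, all but those of AT2G24600, AT2G43620, AT4G12490 and, in gun5, ICL lost their call in at least 1 of 26 alternative settings. The unadjusted p was under 0.05 for 2354 and 2783 probe sets.

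On norflurazon, 5143 probe sets differed between gun1-9 and Col-0, 2354 higher and 2789 lower, and 6246 between gun5 and Col-0, 2480 higher and 3766 lower. At least 2-fold, the larger side was the other one, with 853 higher and 419 lower in gun1-9, and 1051 higher and 296 lower in gun5. With each array centred on its median, 54.2% of the gun1-9 calls and 58.7% of the gun5 calls were higher, against 45.8% and 39.7% with the deposited scaling. Among probe sets with a gene name, the largest positive differences were those of AT3G28270 (5.14), AT1G60590 (4.78), UGT73C1 (4.72), AT2G29370 (4.68) and AT1G09500 (4.58) in gun1-9, and AT3G28270 (4.85), AT4G37560 (4.26), AT2G25510 (4.24), AT1G75460 (3.98) and AT2G15020 (3.91) in gun5. AT3G02480 was lower in both mutants (-6.34 and -6.18), as was AT2G47780 (-4.98 and -5.65). AT3G16670 (-5.50), AT1G23130 (-5.16) and psbC (-4.94) were lower in gun1-9, and DFR (-4.56), AT3G15670 (-4.17) and LEA18 (-4.11) in gun5.

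Values of the other fixed lists follow. Of 4 ABA and cold genes, COR15A and COR15B fell in Col-0 (-1.13 and -1.16), and the list was not called (adjusted p = 0.0906). Of 3 root genes, EXPA7 (1.02) and PYK10 (0.40) rose in Col-0, with adjusted p = 0.139 for the list, and EXPA7 (1.36) and EXPA18 (0.94) rose in gun1-9. Lists with fewer than 3 measured members were not tested. Among them AUR1 of the cell cycle fell in every genotype (-0.81, -1.53 and -1.03), and GI of the circadian clock had -0.32 in Col-0, without a call, and rose by 0.86 in gun1-9 and 0.70 in gun5. HYH, a light signalling gene of the same list, rose by 0.58, 0.73 and 0.70. ZAT10 (STZ) of the reactive oxygen list had 1.35, 1.49 and 0.08 without a call, and RPOTMP (AT5G15700) of plastid gene expression rose in gun1-9 (0.43). The ribosomal gene RPP0B (AT3G09200) rose by 0.61 in Col-0, 0.54 in gun1-9 and 0.43 in gun5, and RPL4A (AT3G09630) had 0.27 in Col-0 without a call. The heat shock gene HSP22 rose by 0.31 in gun1-9 and had -0.24 in Col-0 without a call. HSP26.5 (-0.03 in Col-0) and the defence genes PDF1.2 (-0.44) and THI2.1 (-0.10) were not called in any genotype.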

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

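The tests of mitochondrial transcripts, of RNA quality and of a single deviating Col-0 array, and the lists of plastid-genome probe sets and further seed genes, were chosen after the results were seen.

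The response to norflurazon differed between genotypes for 3476 probe sets (gun1-9 against Col-0), 3831 (gun5 against Col-0) and 1241 (gun1-9 against gun5), each by a test of the difference. The median difference of the flavonoid and anthocyanin list between gun5 and Col-0 was -3.97.

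The plastid-encoded list had median differences of response of -3.04 for gun1-9 against Col-0, 0.85 for gun5 against Col-0 and -4.10 for gun1-9 against gun5. Over all 69 plastid-genome probe sets, treated gun1-9 lay at a median of -4.07 relative to treated gun5. Tables argue against a shift of the authors' normalization shared by probe sets of like brightness, since 775 nuclear probe sets matched on untreated brightness had a median of 0.0304 between the same groups. Normalization to nearly equal medians and quartiles itself holds most nuclear values nearly equal between arrays. That median therefore cannot show whether nuclear messenger RNA as a whole shifted against plastid RNA. The control genes argue against degraded nuclear messenger RNA, since the 3' minus 5' difference of 3 control genes in treated gun1-9 was -0.0518 relative to the mean of the other groups, but the 25S ribosomal RNA control set the same group apart (2147 ± 1124, SD, n = 3, against 78.1 ± 25.5 in treated gun5), so that another difference in the RNA or its labelling stays open. Poor capture of organelle transcripts with short poly(A) tails stays open too, since the 10 mitochondrial probe sets above the dim level had a median log2 change of 0.0986 in gun1-9 on norflurazon (-0.51 to 1.33), but only 2 of them were bright enough to show a fall as large as that of the plastid set, and so does a lower level of plastid transcripts in treated gun1-9.

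The late embryogenesis gene AT3G15670, and ICL, were higher in untreated Col-0 than in untreated gun5 (log2 differences of -3.44 and -4.71 for gun5), and ICL also than in untreated gun1-9. The call was lost in 4 of 26 alternative settings for AT3G15670 in gun5, and in 2 for ICL in gun1-9. In treated mutants against treated Col-0, ICL was at -2.87 (gun1-9) and -3.36 (gun5), and AT3G15670 and LEA18 were at -4.17 and -4.11 (gun5). Seed material or later germination in the Col-0 samples may account for this: in 22 further seed genes, chosen before their own values were seen, 16 were lower in both untreated and 13 in both treated mutants, and camera for the untreated ones gave adjusted p = 4.88e-05 (gun1-9) and 7.06e-05 (gun5), but adjusted p = 0.937 and 0.950 with an estimated correlation. Both mutants are compared with the same Col-0 arrays, so a gene lower in 1 mutant tends to be lower in the other. The share of all probe sets lower in both was not counted. The median differences were -0.182 (gun1-9) and -0.164 (gun5) untreated and -0.207 and -0.205 treated, within the bound of 0.5 set in advance as speaking against it, yet 17 of the 22 genes lay within 1 log2 unit of the dim level in untreated Col-0, among them the seed storage gene OLEO3 at 5.22 ± 0.986 (SD, n = 3), so the bound should have been set on genes above that level, and the explanation stays open. Without Col-0 control replicate 1 the median lay 0.0915 above the mutants, which for the same reason does not settle whether 1 array carries the pattern, and a difference of genotype stays open, untested.

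The control probe set for 25S ribosomal RNA, outside the tested set, was higher by 5.69 (log2) in treated than in untreated gun1-9. The control probe set U12639, whose target is not given in the sources used here, was higher by 7.28 (log2) in untreated gun5 than in untreated Col-0, at 596.6 ± 68.0 (SD, n = 3), and was at 3.78 ± 0.554 in treated gun5. It was also low in treated Col-0 (2.78 ± 0.215) and in untreated and treated gun1-9 (2.71 ± 0.333 and 2.94 ± 0.409). Whether untreated and treated gun5 differ in more than norflurazon was not tested. Every response and difference of response of gun5 rests on these arrays.

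Other splits of the arrays were refitted on the arrays compared. For each comparison of 3 against 3 arrays only 10 splits exist, too few for a share under 0.05, and the real split alone (1 of 10) reached its count. The real counts were 8482, 7595 and 6130 for the norflurazon responses of Col-0, gun1-9 and gun5, 1 and 123 for untreated gun1-9 and gun5 against Col-0, and 5194 and 5471 for the treated mutants against Col-0, with a highest other count of 0 in each. For the difference of response, 100 of 200 splits were drawn. For gun1-9 against Col-0, 1 of 100, the real one, reached 3202 (highest other 3120), and for gun5 against Col-0 2 of 100 reached 3626 (highest other 4438), shares under 0.05. For gun1-9 against gun5, 6 of 100 reached 1172 (highest other 1430), so chance is not excluded by this count. These shares say little about the difference of response itself, because the count follows whether the treated arrays of a genotype stay together. The other splits with as many calls, 1 for gun5 against Col-0 and 5 for gun1-9 against gun5, all kept the treated arrays of each genotype together, a structure of the samples. Among splits that mixed the treated genotypes, the highest counts were 0, 6 and 5, in the order above.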

How the results depend on the processing

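The fit without plastid-genome probe sets was chosen after the results were seen. No called list test, called named gene or median turned direction. The larger share of calls did change sides. With centring, 49.7% of calls were higher for the Col-0 response (61.6% with the deposited scaling), 54.2% for treated gun1-9 (45.8%) and 58.7% for treated gun5 (39.7%) against Col-0. For the gun5 difference (51.8%) it was 48.5% with quantile normalization and 48.0% with log2(intensity + 16). At least 2-fold, it was 39.1%, 44.7% and 42.8% for the responses, 49.1% for untreated gun5, and 67.1% and 78.0% for treated gun1-9 and gun5. Without Col-0 control replicate 3 it was 51.9% for untreated gun1-9 (36.7%), and without Col-0 control replicates 1 and 2 49.8% and 49.3% for untreated gun5 (52.1%). The cause was not tested unless stated.

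Deviations from the group means correlated across probe sets between -0.113 and 0.190 for 45 same-numbered pairs of arrays (median 0.0462, 7 over 0.1) and between -0.158 and 0.109 for 90 other pairs (median -0.0169, 3 over 0.1). Since not every same-numbered pair was over 0.1, the numbers were not taken to pair the arrays. As a hint of shared structure, 14 of 18 arrays correlated best with their own number, and replicate 1 had the highest plastid-genome median in 6 of 6 groups. With the replicate block, the counts were 9034, 8383 and 6746 for the responses of Col-0, gun1-9 and gun5, 3587, 3969 and 1331 for their differences, 106 and 408 for the untreated and 5275 and 6449 for the treated mutants against Col-0, and 2257 shared differences. With it 0 of 238 results changed their call or direction. Without the plastid-genome probe sets the differences of response were 3400, 3787 and 1156.

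Requiring at least 2-fold, which by construction removes calls, left 2427, 2148 and 1513 calls for the norflurazon responses, 1485, 1611 and 494 for the differences of response (gun1-9 and gun5 from Col-0, gun1-9 from gun5), 39 and 110 for untreated and 1272 and 1347 for treated gun1-9 and gun5 against Col-0, and 886 shared differences against 2164. For untreated gun1-9 and gun5 against Col-0, a fit on the arrays compared gave 1 and 123 calls, a fall whose cause was not tested, and trend and robust settings gave 141 for gun1-9. Leaving out 1 array gave 27 to 120 for gun1-9 and 160 to 411 for gun5. Counts moved over 1.5 times without Col-0 control replicate 3 (27 and 180), gun1-9 control replicate 3 (34 for gun1-9), gun5 control replicate 3 (59 and 160), and gun5 control replicates 1 and 2 (196 and 234 for gun5).

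The median log2 change in gun1-9 of genes lower in Col-0 was -0.85 with quantile normalization and -0.85 with centring, -0.77 with log2(intensity + 16), and -0.87 to -0.83 with 1 array left out. For genes higher in Col-0 it was 1.02 in gun1-9 and 0.92 in gun5 with centring, 0.88 in gun5 with log2(intensity + 16), and 0.92 to 0.99 (gun1-9) and 0.73 to 0.83 (gun5) with 1 array left out. Of genes chosen in gun1-9, the medians were -1.50 and 1.31 in gun1-9 and -1.05 and 0.94 in gun5, and of genes chosen in gun5 -1.45 and 1.24 in gun1-9 and -1.40 and 1.27 in gun5.

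List tests lost their call with an estimated correlation in Col-0 for plastid-encoded (adjusted p = 0.0893), flavonoid (0.0797) and mitochondrial stress genes (0.0524), in gun1-9 for antenna (0.0581) and flavonoid genes (0.198), in gun5 for Calvin cycle (0.112), tetrapyrrole (0.140) and flavonoid genes (0.211), and for the gun5 difference of plastid-encoded genes (0.0758). With the filter on the lowest means over all arrays, mitochondrial stress in Col-0 (0.0735) and flavonoid genes in gun1-9 (0.111) lost it, and with log2(intensity + 16) flavonoid genes in gun1-9 (0.0625) and gun5 (0.0858). The flavonoid difference between gun1-9 and Col-0 gained a call with centring (0.0412), log2(intensity + 16) (0.0278) and trend (0.0495). ABA and cold genes in Col-0 gained one on the arrays compared (0.0483). With 1 array left out, adjusted p ranged from 0.0214 to 0.0622 (flavonoid, gun1-9), 0.0471 to 0.416 (plastid-encoded, gun5), 0.0408 to 0.192 (ABA and cold, gun5), 0.0216 to 0.167 (flavonoid, gun1-9 difference), 0.0316 to 0.569 (tetrapyrrole) and 0.0316 to 0.696 (flavonoid) for untreated gun1-9, and 0.0495 to 0.837 (plastid-encoded) and 0.0495 to 0.446 (ABA and cold) for untreated gun5. Of 150 results of named genes, 17 lost their call in at least 1 of 26 settings, all but AT4G10270 in the untreated comparisons. Named results whose probe set was removed by the filter on the lowest means had no test in that setting. Signal over background limits dim genes: a fold that starts near the dim level depends on the constant added.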

Other observations

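The lists described here were tested only after the data were seen. Among 17 symbol families, camera called the UGT family of glycosyltransferases for the difference of response between gun1-9 and Col-0: of 47 probe sets, 10 were higher and 1 lower (median 0.10, adjusted p = 0.00098, and adjusted p = 0.0112 with an estimated correlation). Over all 22746 probe sets, 1835 were higher and 1641 lower. UGT73C1 and UGT84A3 had been seen among the largest named differences before the family was tested, and both stayed in the test. The test is therefore not independent support for a response of the whole family. Besides UGT73C1 and UGT84A3, the higher UGT probe sets included UGT76E11 (2.60), UGT76C2 (2.32), UGT73B1 (1.99) and UGT87A2 (1.96), and UGT78D1 was lower (-1.93). In gun5 9 were higher and 4 lower (adjusted p = 0.113). Between gun1-9 and gun5 6 were higher and 0 lower (adjusted p = 0.00126, and adjusted p = 0.0113 with an estimated correlation). Of 29 serine carboxypeptidase-like (SCPL) probe sets, 14 fell in gun1-9 on norflurazon and 0 rose (adjusted p = 9.74e-05, and adjusted p = 0.0102 with an estimated correlation), with scpl46 at -2.13. In gun5 12 fell and 1 rose (adjusted p = 0.00174, and adjusted p = 0.0555 with an estimated correlation). In Col-0 7 fell and 1 rose (adjusted p = 0.0977), and for the difference of response from Col-0 the list was not called in gun1-9 (adjusted p = 0.0940) or gun5 (adjusted p = 0.385). The families GST, NRP, IQD, EXP and XTH were called in at least 1 contrast, and in none with an estimated correlation. The remaining families are not described here. Of 23 mitochondrial-genome probe sets 8 rose in Col-0, 2 in gun1-9 and 4 in gun5, and the list was not called.

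Within the plastid genome, all 20 psa and psb probe sets fell in Col-0 on norflurazon (median -1.28), as did all 6 atp (-1.35) and 9 of 10 ndh probe sets (-1.77), whereas 1 of 4 rpo (-0.23) and 3 of 15 rpl and rps probe sets (-0.14) did. In gun1-9 all 4 rpo (-4.05) and 14 of 15 rpl and rps probe sets (-3.57) fell. Of 6 pet probe sets 3 fell in Col-0 (-0.49) and 6 in gun1-9 (-2.84). With an estimated correlation no group was called in Col-0 (adjusted p = 0.245 for psa and psb, atp and ndh, 0.531 for pet, 0.745 for rpo and 0.759 for rpl and rps), and in gun1-9 adjusted p lay between 0.0102 and 0.0172. No test compared the groups with each other. Over all 69 plastid-genome probe sets, 47 fell in Col-0, 67 in gun1-9 and 11 in gun5, where 3 rose.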
